A study of Solanum tuberosum with 6 samples.

How the data were processed

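The deposited values came from 6 two-colour arrays, 3 for day 1 and 3 for day 3. Per the labels' protocols, plants were acclimatized for 2 months at 21 and 18 degrees C by day and night with 12 hours of light at 40 micromoles per square metre and second. By the same protocols, RNA was taken from 100 mg of the first and second leaves, and samples with an RNA integrity number under 7 were excluded. For each sample, 15 micrograms of RNA were labelled with Cy3 or Cy5. The log2 ratios were deposited by the authors as one value per clone and array. Scanner, background correction, normalization, spot filters and log base are not given in the sources used here, and base 2 was taken because ratios of this size on base 10 would exceed a million-fold. The median ratio of each array lay between -0.005 and 0.049. The deposited table also held the authors' p-value of a one-sample test per clone and day, and a recomputed test gave a p-value within 0.001 for 9311 of 10181 clones on day 1 and 7993 of 9072 on day 3.

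The annotated table and the value table were joined by their 6 values per clone, which matched for all 10499 rows. In 8 clones the values were shared by a pair of rows, which does not alter any value. Gene names are the table's own annotation, which names the most similar known gene, so a clone carries the name of a gene from another species in many cases. The clones could not be placed on a genome from the tables used here. No intensities were used, so the planned background correction and loess did not apply and the ratios entered as deposited. The planned turning of ratios by dye was left out, because arrays of the same day and opposite dye orientation already correlated above 0. A dye effect per clone could give such a correlation in unturned ratios too.

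The ratios of all 6 arrays were fitted by least squares, separately for each pattern of missing values, and tested with limma 3.58.1 in R 4.3.3, with a coefficient for each day and a dye term per clone (3 coefficients and 3 residual degrees of freedom where all arrays were measured). Empirical Bayes moderation of the variances followed, with Benjamini-Hochberg adjustment over the clones tested, at an adjusted p under 0.05. The dye term was included because a dye effect does not cancel when salt is in Cy3 on 2 arrays and in Cy5 on 1 array of a day. It had an unadjusted p under 0.05 in 1823 of 9742 clones, where chance gives 487, and passed adjustment in 0. A clone was tested for a day when it was measured on at least 2 arrays of that day, and for the difference and the average when this held for both days. This minimum was set after the data were examined. All p-values are two-sided. Those of single clones, and the SEs, measure the spread between biological replicates, with 1 estimate per clone over both days. An SE can thus be too small for the day on which a clone varied more, and too large for the other day. The comparison of the days is a contrast of the same fit.

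Gene lists were fixed before the data were examined as word patterns applied to the annotation, 26 in all. Of these, 25 with at least 5 clones were tested with camera at its preset correlation of 0.01, on the clones measured on all 6 arrays, and adjusted over the lists within a comparison. At that setting camera sets a list's clones against the other clones, and its p-values do not measure the spread between replicates. Counts within a list cover all tested clones. Genes were named by a rule fixed in advance. For each day and for the average, it took the 10 largest rises and 10 largest falls among annotated clones past the threshold with the same sign on every array, one clone per annotation. It also took up to 4 members of a list with the smallest p, and for the difference between days the 5 clones per direction with the smallest p. The text gives the leading ones of these. A few word patterns matched by accident (methionine enzymes in the defence list, replication proteins in the transport list), and the lists were kept as fixed, with cleaned lists among the alternatives.

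The fit was tested on simulated ratios with the real spread, dye terms and missing values, with 200 clones changed on each day. On day 1 it called 48.4% of the clones changed by 1 on the log2 scale and 0 of those changed by 0.5, among 9738 clones, and on day 3 51.8% and 3.4% among 9032 clones. These shares do not carry over to the data, because the adjustment depends on the number of changed clones. The data gave 1800 calls on day 1 and 579 on day 3. On the 7632 clones measured on all arrays the coefficients and the day 1 p-values differed from those of limma's lmFit and eBayes by less than 1e-06. Other tools were Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

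Alternatives were a fit without the dye term, scaling of the arrays to equal median absolute deviation, only clones measured on all arrays, an adjusted p under 0.1, a replicate block, each array left out in turn, the arrays of a day alone, camera with an estimated correlation and fry. Centring of each array on its median, the authors' deposited test, cleaned lists and a list of sterol and glycoalkaloid synthesis were added after the data were examined.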

Results

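Leaves of the potato (Solanum tuberosum) cultivar PS3 were compared between plants watered with 75 mL of 150 mM NaCl and plants watered with the same volume of tap water, 1 and 3 days after the watering. The design asks how gene expression in the leaf differs between salt and control at each time, and whether that difference changes between the days. Each of 6 two-colour cDNA arrays carried leaf RNA of salt-watered plants in one dye and of control plants of the same day in the other, so that every value is a log ratio between both treatments. There were 3 arrays per day, each from its own biological replicate, and the leaves of day 1 and day 3 came from different plants. Salt RNA was in Cy3 on replicates 1 and 3 of each day and in Cy5 on replicate 2.

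The table held 10499 clones, of which 7525 carried an annotation naming a similar gene, often from another species. The number of clones measured per array was 10139, 9869 and 10012 on day 1 and 10381, 8934 and 7867 on day 3, and 7632 clones were measured on all 6 arrays. Across clones, which are not independent replicates, the arrays of day 1 correlated with r between 0.506 and 0.809 and those of day 3 with r between 0.475 and 0.639. Replicate 1 of day 3 stood apart, with r of 0.031, -0.086 and 0.006 against the day 1 arrays, in the order of their replicates. In the same order, replicate 2 of day 3 gave 0.222, 0.436 and 0.081 and replicate 3 gave 0.486, 0.259 and 0.476. The number of arrays limits the precision of every value below.

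All ratios are given as salt over control. This direction is likely and not stated: the labels mark the control as the reference channel and name control before salt, and arrays of opposite dye orientation correlated above 0 within each day (r of 0.577 and 0.506 on day 1 and 0.475 and 0.639 on day 3), so that the ratios of a day were taken to run one way already. If the ratios ran the other way, each rise would be a fall. The agreement of opposite orientations does not settle this, because a dye effect per clone could also make unturned ratios correlate above 0. In that case the changes given below would reflect the dyes and not salt. Replicates 1 and 3, of the same orientation, correlated with r = 0.809 on day 1 and 0.523 on day 3. The base of the logarithm is not stated either, and 2 was taken, so folds hold only for that base.

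On day 1 the largest falls included clones of carbon fixation. A GAST1-like clone (STMJC16), related to a gibberellin-responsive tomato gene, fell by 4.04 (SE 0.24, adjusted p = 5.3e-05), and a germin-like clone (STMCM83) fell by 3.88 (SE 0.18, adjusted p = 2.11e-05). All 5 clones sharing 1 annotation as maize carbonic anhydrase, which interconverts carbon dioxide and bicarbonate, were lower, with log2 ratios from -3.45 to -3.05. Of 20 clones sharing 1 annotation as small subunits of Rubisco, the carbon-fixing enzyme, 18 were lower, the most strongly STMIW88 at -2.75. Clones with differently worded annotations are not in these counts. Every clone given here as a largest rise or fall of a day had the same sign on each array of that day on which it was measured, as the rule for naming it required.

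Among 82 clones of photosystems and light harvesting, 62 were lower on day 1, 1 was higher and 19 passed neither way, with a median log2 ratio of -1.01. Examples were the light-harvesting protein CP24 (STMIY56, -2.16, SE 0.14), the oxygen-evolving enhancer protein (STMCP64, -1.69, SE 0.11) and a chlorophyll a/b-binding protein (STMCK76, -1.47, SE 0.11). In carbon fixation and photorespiration 46 of 64 clones were lower and 0 were higher, with a median of -1.20. Of the lower clones, 18 shared 1 Rubisco annotation and 5 shared 1 carbonic anhydrase annotation, so some genes may be counted repeatedly. In chlorophyll and carotenoid synthesis 17 of 25 clones were lower and 1 was higher, including protochlorophyllide oxidoreductase (STMDP32, -1.55) and the magnesium-protoporphyrin cyclase (STMJD64, -1.18). Among plastid ribosomal proteins 24 of 29 clones were lower, with a median of -1.03, among them L24 (STMJN60, -1.39). Adjusted over the list alone, the lower clones numbered 64, 47, 18 and 25 in these lists. The higher clones adjusted over the list alone numbered 1, 0, 2 and 0. Camera, which compares a list with the other clones, gave adjusted p = 8.06e-25, 4.01e-18, 2.41e-08 and 5.86e-13 in the same order. With an estimated correlation between clones the adjusted p was 0.274 for the photosystem list and 0.441 for each of the other lists.

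Genes of nitrogen and sulfur assimilation were also lower on day 1 in 7 of 39 clones, with 1 higher (7 and 1 adjusted over the list alone). They included sulfate adenylyltransferase (STMHU37, -1.24), which activates sulfate, and nitrite reductase (STMCG91, -1.29). In the list of cell wall and cell expansion 26 of 89 clones were lower and 5 higher (28 and 6 adjusted over the list alone). Pectin methylesterase, which modifies wall pectin, fell by 2.54 (STMIU31, SE 0.13), an alpha-expansin, a wall-loosening protein, fell by 1.81 (STMDH16) and a proline-rich protein fell by 1.65 (STMGL17). By camera the adjusted p was 0.000192 and 0.0025 for these lists, and with an estimated correlation the adjusted p was 0.441 and 0.476. In lipid transfer, wax and fatty acid synthesis 21 of 89 clones were lower and 8 higher (27 and 9 adjusted over the list alone), with a palmitoyl desaturase (STMCP71) at -1.46. For this list camera gave adjusted p = 0.0288, which became 0.062 without replicate 1 of day 1 (adjusted p = 0.441 with an estimated correlation). Among antioxidant and redox enzymes 23 of 113 clones were lower and 5 higher (28 and 6 adjusted over the list alone), with thioredoxin peroxidase (STMCO25) at -1.79 and thioredoxin h (STMHN77) at 1.06. The list had camera adjusted p = 0.00603, and 0.0647 without replicate 1 of day 1 (adjusted p = 0.476 with an estimated correlation). In the list of commonly used reference genes 7 of 22 clones were lower and 0 higher (11 and 1 adjusted over the list alone), led by tubulin clones such as STMBB10 at -1.27. The reference genes had camera adjusted p = 0.0154, and 0.0647 without replicate 1 of day 1 (adjusted p = 0.476 with an estimated correlation). Jasmonate and ethylene synthesis had 6 of 18 clones lower and 1 higher (7 and 3 adjusted over the list alone), with camera adjusted p = 0.0153 (adjusted p = 0.476 with an estimated correlation). Without replicate 2 of day 1 it was 0.0616, and the array medians were -0.08, -0.30 and 0.02. Cytosolic ribosomal proteins had 11 of 125 lower and 1 higher (9 and 1 adjusted over the list alone), with camera adjusted p = 0.0125 (adjusted p = 0.692 with an estimated correlation). Without replicate 1 of day 1 it was 0.552, and the array medians were -0.40, 0.04 and -0.07.

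The largest rises on day 1 were a hypothetical protein (STMEK04, 2.73, SE 0.37), a class 1 chitinase (STMHO72, 2.56), a clone like Arabidopsis protein At5g25560 (STMIA28, 2.53, SE 0.22), VDAC3.1, an outer membrane channel of mitochondria (STMGI75, 2.53), and a WD-repeat protein (STMCF40, 2.46). Next came a wound-induced transcript (STMIW38, 2.31, SE 0.15, adjusted p = 8.19e-05), ethylene response factor 5 (STMIK39, 2.29, SE 0.20) and cytosolic nucleoside diphosphate kinase (STMGY04, 2.28). They also included a CCR4-associated factor (STMDD59, 2.24) and vacuolar processing enzyme, a cysteine protease (STMHL75, 2.12). A second clone annotated as class 1 chitinase was lower, at -1.22. In the list of dehydration and abscisic acid response 14 of 50 clones were higher and 1 lower (16 and 3 adjusted over the list alone). Its leading members were 2 clones like the dehydration-induced RD22, at 1.35 (STMDG60) and 1.34 (STMCR18), and a low temperature and salt responsive protein at 0.96 (STMEV23, SE 0.12). Among transcription factors 36 of 217 clones were higher and 9 lower (38 and 10 adjusted over the list alone). They included homeobox clones STMEF08 (1.54) and STMEK10 (1.47), a NAC domain protein (STMFB46, 1.25) and a WRKY protein (STMCN79, 1.71). In proteolysis and ubiquitin 26 of 161 clones were higher and 7 lower (26 and 7 adjusted over the list alone), with cysteine proteases STMCN29 (1.06) and STMCJ34 (1.02) in front. For these lists camera gave adjusted p = 0.00148, 0.000374 and 0.00304, and with an estimated correlation the adjusted p was 0.441 for each.

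Of 103 clones of heat shock proteins and chaperones, 22 were higher and 14 lower on day 1 (24 and 16 adjusted over the list alone), with Hsp90-like clones STMHA96 (1.39) and STMCV54 (1.38) among the higher. Camera gave adjusted p = 0.143. The invertase inhibitor STMJC15 rose by 1.90 (SE 0.12, adjusted p = 6.53e-05). The list of starch and sucrose metabolism as a whole had 7 higher and 8 lower clones of 47 (9 and 10 adjusted over the list alone, camera adjusted p = 0.585). Histone H1 (STMGF62) rose by 1.88 in a list of histones and cell division with 8 of 69 clones higher and 3 lower (8 and 3 adjusted over the list alone, camera adjusted p = 0.0876). Aquaporin clone STMEA30 fell by 1.80, in a list of ion and water transport with 6 of 53 clones lower and 3 higher (6 and 3 adjusted over the list alone, camera adjusted p = 0.105, and 0.0384 without replicate 2 of day 1). With an estimated correlation this list had adjusted p = 0.551.

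In all, 790 of 9738 tested clones were higher and 1010 lower on day 1 at an adjusted p under 0.05 with limma, and 143 and 360 of them had ratios beyond 1. The 1422 annotated calls of day 1 carried 1054 distinct annotations. The counts rest on each array of the day: 407 higher and 575 lower passed without replicate 1, 169 and 367 without replicate 2, and 419 and 653 without replicate 3. In the authors' deposited table, 2033 clones had p under 0.05 in a one-sample test on day 1, and 0 passed after Benjamini-Hochberg adjustment.

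**Figure D1:**
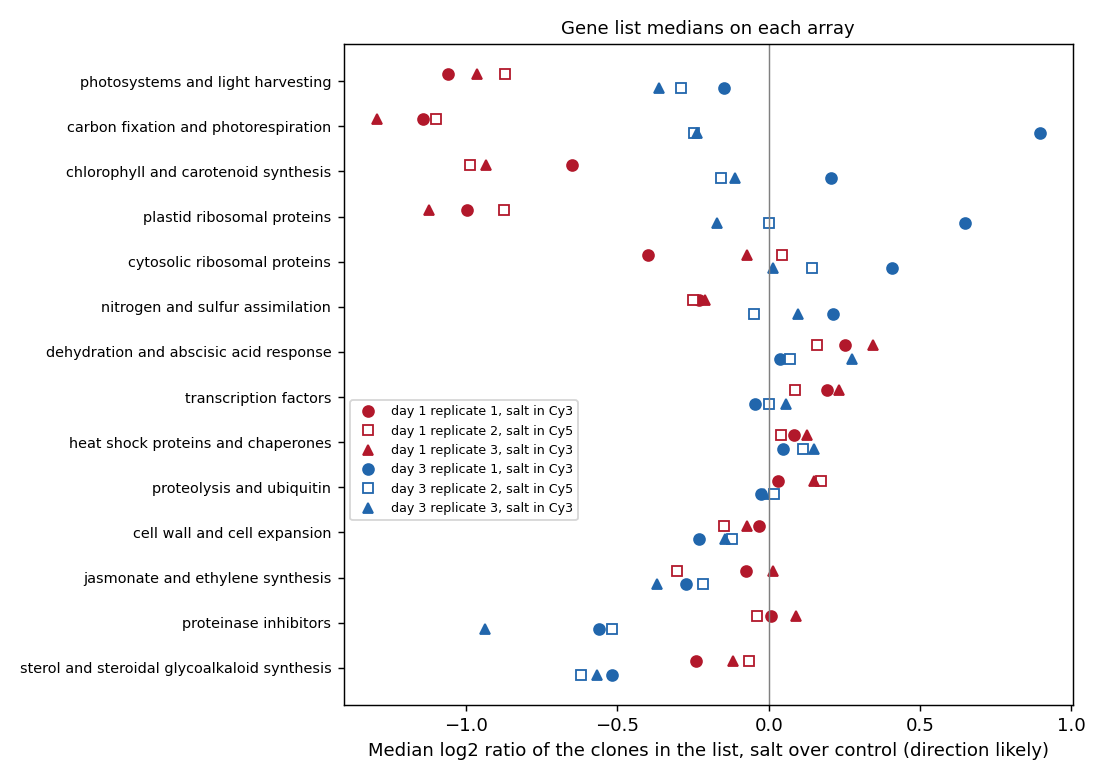
Median log2 ratio of salt over control (horizontal axis, direction likely) of the clones in 14 gene lists on each of the 6 arrays, with day 1 in red and day 3 in blue, a marker shape per replicate, and open markers for salt in Cy5. The carbon fixation list lies between -1.29 and -1.10 on the day 1 arrays and at 0.90, -0.25 and -0.24 on the day 3 arrays, and the sterol list, written after the data were seen, lies between -0.62 and -0.52 on day 3.

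On day 3 the largest falls included a lectin, a sterol enzyme and a proteinase inhibitor. A chitin-binding lectin (STMCQ19) fell by 5.30 (SE 0.32, adjusted p = 1.99e-05), after a fall by 2.70 on day 1. Its SD between arrays was 1.077 on day 3 and 0.416 on day 1, while the SE pools both days. For STMGI29, named below, the SD was 0.405 on day 3 and 0.551 on day 1. A clone like the cotton fibre elongation protein Ghfe1 (STMCH16) fell by 4.48 (SE 0.15, adjusted p = 1.03e-06), and DIMINUTO, a sterol reductase (STMGG42), fell by 3.44 (SE 0.14, adjusted p = 1.9e-06). Others were a proteinase inhibitor (STMCP16, -3.60), gamma tubulin (STMGM17, -3.59), cytochrome P450 clones STMGN13 (-3.52) and STMCG85 (-3.47), and an acid phosphatase (STMCI91, -3.49). A hypothetical tomato protein was at -5.05 (STMGI29) and a clone like Arabidopsis T1B9.26 at -3.14 (STMDB68).

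Proteinase inhibitors, which protect leaves against the digestive enzymes of insects, were lower on day 3 in 11 of 22 clones and higher in 0 (13 and 1 adjusted over the list alone), with a median of -0.52. Proteinase inhibitor I fell by 2.56 (STMCM05, SE 0.23) and a metallocarboxypeptidase inhibitor fell by 2.98 (STMCG57, SE 0.33). In jasmonate and ethylene synthesis 6 of 16 clones were lower and 1 higher (6 and 1 adjusted over the list alone). Among the lower were clones of 13-lipoxygenase (STMCN05, -1.98, and STMDB62, -1.78), an early enzyme of jasmonate synthesis. Also lower was hydroperoxide lyase (STMCD19, -1.57), which the list's words matched although it does not itself make jasmonate. In cell wall and cell expansion 16 of 82 clones were lower and 3 higher (21 and 3 adjusted over the list alone). It was led by pectin methylesterase (STMIU31, -2.67, SE 0.13) and an extensin-like protein (STMCR06, -1.28). The adjusted p by camera was 1.58e-07, 8.27e-05 and 1.13e-06 for these lists, and with an estimated correlation the adjusted p was 0.587 for each.

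Photosystem and light-harvesting clones were lower on day 3 in 14 of 82 and higher in 0 (21 and 1 adjusted over the list alone), with a median of -0.27 and light-harvesting clones STMCY82 at -1.06 and STMIU17 at -0.76. Camera gave adjusted p = 4.36e-08 (adjusted p = 0.587 with an estimated correlation), and the medians on replicates 1, 2 and 3 were -0.15, -0.29 and -0.36. In carbon fixation and photorespiration 1 of 64 clones was higher, Rubisco activase (STMCF73, 1.13), and 0 were lower (1 and 0 adjusted over the list alone), and the list's medians on replicates 1, 2 and 3 were 0.90, -0.25 and -0.24. This list had camera adjusted p = 0.521 on all arrays, 5.45e-05, downward, without replicate 1 of day 3, and 0.000722 and 5.77e-05, upward, without its replicates 2 and 3. With an estimated correlation its adjusted p on all arrays was 0.981. Of 29 plastid ribosomal clones 0 passed on day 3 with limma (0 adjusted over the list alone, camera adjusted p = 0.24), with array medians of 0.65, 0.001 and -0.17. Without replicate 2 or 3 of day 3 the camera value of this list became 0.0467 or 0.000105, upward (adjusted p = 0.981 with an estimated correlation). Cytosolic ribosomal proteins had a median of 0.20 with 1 of 124 clones higher and 2 lower (1 and 1 adjusted over the list alone) and array medians of 0.41, 0.14 and 0.01. For this list camera gave adjusted p = 5.29e-06, which became 0.157 without replicate 1 of day 3 (adjusted p = 0.829 with an estimated correlation).

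The largest rises on day 3 were a cation exchanger of the CAX type (STMHE26, 2.83, SE 0.24, adjusted p = 0.000164), the hypothetical proteins STMEK04 (2.67) and STMHE41 (2.36, adjusted p = 0.000136), and cyclic nucleotide-gated ion channel 4 (STMIT24, 2.18, SE 0.13, adjusted p = 1.46e-05). The others were the CCR4-associated factor STMDD59 (2.02), a lipid-transfer protein (STMGR44, 1.86), ethylene response factor 5 (STMIK39, 1.54), pathogenesis-related protein 10 (STMDW19, 1.51), sulfate adenylyltransferase (STMDV93, 1.49) and ascorbate oxidase (STMER81, 1.46). The SD of STMHE26 between arrays was 0.759 on day 3 and 0.186 on day 1. All 3 clones with the annotation of STMHE26 and all 3 with that of STMDV93 were higher. In the dehydration and abscisic acid list 7 of 44 clones were higher and 1 lower (13 and 2 adjusted over the list alone), with the RD22-like clones STMCR18 at 0.97 and STMDG60 at 0.87 and protein phosphatase 2C (STMGP26) at 0.92. This list had camera adjusted p = 0.14, and 0.0288 without replicate 1 of day 3 (adjusted p = 0.829 with an estimated correlation). Tyramine hydroxycinnamoyl transferase rose (STMIP44, 0.83) in a phenylpropanoid list with 3 of 38 clones higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.6). Endochitinases fell (STMIX82, -2.10; STMIS93, -1.48) while pathogenesis-related protein 10 rose, in a defence list with 8 of 126 clones higher and 12 lower (12 and 13 adjusted over the list alone, camera adjusted p = 0.6), some of whose members were methionine enzymes matched by part of a word. This list's median was 0.06 and its mean -0.02, while camera pointed upward. Markers of epidermis and trichomes, cell types that a whole leaf also holds, had 5 of 11 clones higher and 1 lower on day 3 (5 and 2 adjusted over the list alone, camera adjusted p = 0.0606). Of the higher clones 3 shared the lipid-transfer annotation of STMGR44, so a changed share of these cell types cannot be read from the list. The camera value of these markers was 0.0459 without replicate 2 of day 1 and 0.00585 without a dye term (adjusted p = 0.821 with an estimated correlation).

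Of 9032 clones tested on day 3, 177 were higher and 402 lower, 42 and 162 of them beyond 1. With arrays scaled to equal spread 351 were higher and 563 lower, and without a dye term 114 and 316. Without replicate 2, the only array of that day with salt in Cy5, 28 were higher and 143 lower, and the higher clones numbered 278 without replicate 1 of day 3, 100 without replicate 1 of day 1 and 106 without replicate 2 of day 1. STMEK04 and STMIK39 no longer passed on day 3 without its replicate 2. The authors' deposited table had 1017 clones with p under 0.05 on day 3, of which 1 passed after Benjamini-Hochberg adjustment.

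Genes of photosynthesis were among those whose salt response differed between the days. The ratio was higher on day 3 than on day 1 in 41 of 64 clones of carbon fixation and photorespiration, in 39 of 82 photosystem clones, in 18 of 29 plastid ribosomal clones and in 14 of 25 clones of chlorophyll and carotenoid synthesis. The median differences were 1.40, 0.68, 1.18 and 0.98, and adjusted over the list alone the higher clones numbered 48, 54, 25 and 15. Lower on day 3 than on day 1 were 0, 0, 0 and 1 clones (2, 0, 0 and 2 adjusted over the list alone). In each of these lists replicate 1 had the highest median of the day 3 arrays, as given above and, for chlorophyll and carotenoid synthesis, at 0.21 against -0.16 and -0.11. For carbonic anhydrase STMCR16 the ratio was -3.17 ± 0.31 (SD, n = 3) on day 1 and 0.02 ± 0.62 (SD, n = 3) on day 3, a difference of 3.18 (SE 0.26, adjusted p = 0.000268). Sulfur and nitrogen assimilation was higher on day 3 in 9 of 37 clones, and cytosolic ribosomal proteins in 13 of 124 (12 and 13 adjusted over the list alone). Lower were 0 and 1 clones of these lists, also adjusted over the list alone. The adjusted p of camera was 2.86e-20, 1.11e-15, 8.82e-14, 7.68e-06, 4.83e-05 and 1.01e-07 for these lists in the order named. With an estimated correlation the adjusted p was 0.533 for photosystems, 0.68 for cytosolic ribosomal proteins and 0.63 for each of the others.

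Proteinase inhibitors were lower on day 3 than on day 1 in 9 of 22 clones and higher in 1 (10 and 2 adjusted over the list alone), with camera adjusted p = 0.0125 (adjusted p = 0.668 with an estimated correlation). Proteolysis and ubiquitin (20 of 157 clones) and transcription factors (15 of 204 clones) also had lower ratios on day 3 (23 and 14 adjusted over the list alone), with 1 and 3 clones higher by either adjustment, and camera adjusted p = 0.0017 and 0.00135 (adjusted p = 0.63 for each with an estimated correlation). Ghfe1 (STMCH16) went from -0.62 ± 0.10 to -4.49 ± 0.34 and DIMINUTO (STMGG42) from -0.35 ± 0.17 to -3.48 ± 0.28 (mean ± SD, n = 3 per day). The ion channel clone STMIT24 went from 0.17 ± 0.19 to 2.23 ± 0.26. An epidermis-specific glycoprotein (STMDF40) went from -1.44 ± 0.31 to 0.81 ± 0.04. The list of epidermis and trichome markers had 3 of 11 clones higher on day 3 than on day 1 and 1 lower (4 and 1 adjusted over the list alone). Its camera adjusted p was 0.0693, and 0.0147 without a dye term (adjusted p = 0.68 with an estimated correlation).

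Over all clones 578 of 9028 had a higher ratio on day 3 and 462 a lower one. Without replicate 1, 2 or 3 of day 1 these counts were 134 and 177, 248 and 174, or 263 and 227, and without replicate 2 of day 3 they were 372 and 236.

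**Figure D2:**
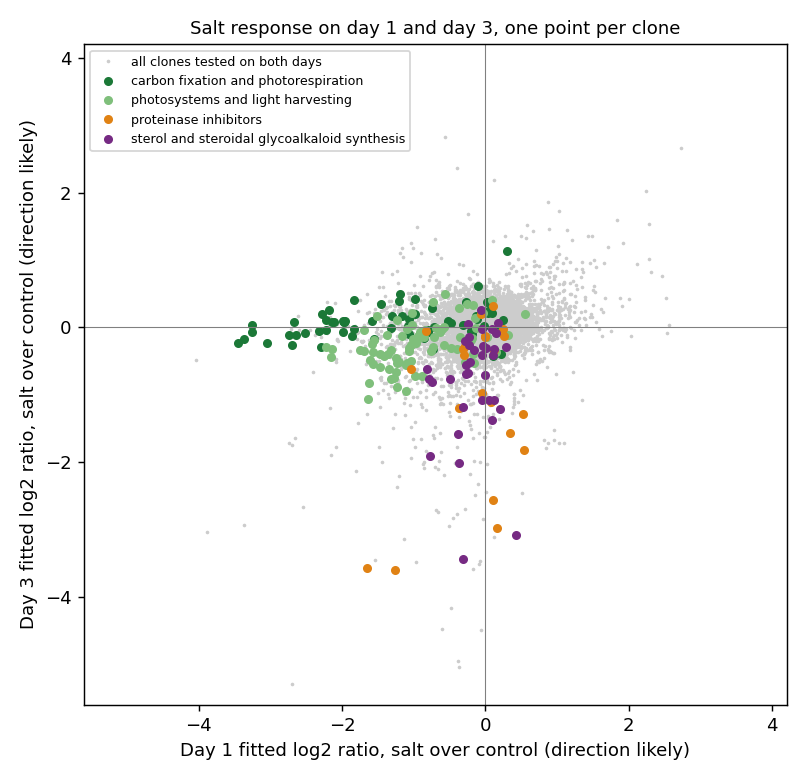
Fitted log2 ratio of salt over control (direction likely) on day 1 (horizontal axis) and day 3 (vertical axis), one grey point per clone tested on both days, with 4 gene lists in colour. Carbon fixation clones lie far to the left near 0 on the vertical axis, with a day 1 median of -1.20 and a day 3 median of 0.07, and proteinase inhibitors and sterol clones extend downward, with day 3 medians of -0.52 and -0.59.

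Averaged over both days, 655 clones were higher and 956 lower. The largest falls were the chitin-binding lectin (STMCQ19, -4.00, SE 0.23), the germin-like clone (STMCM83, -3.46, SE 0.13), a hypothetical tomato protein (STMCL06, -2.67, SE 0.15), a proteinase inhibitor (STMIY57, -2.61), pectin methylesterase (STMIU31, -2.60, SE 0.10) and Ghfe1 (STMCH16, -2.55). The largest rises were STMEK04 (2.70, SE 0.27), the CCR4-associated factor STMDD59 (2.13), ethylene response factor 5 (STMIK39, 1.91, SE 0.15) and nucleoside diphosphate kinase (STMGY04, 1.64). They were followed by a DNA-binding protein (STMEF49, 1.58), the wound-induced transcript (STMIW38, 1.56), vacuolar processing enzyme (STMHL75, 1.53), a WRKY protein (STMCN79, 1.45) and a RING finger protein (STMIU24, 1.39). Photosystem clones were lower in 57 of 82 and dehydration and abscisic acid clones higher in 14 of 44 (64 and 16 adjusted over the list alone), with camera adjusted p = 1.62e-23 and 0.00151 (adjusted p = 0.296 and 0.435 with an estimated correlation). Without replicate 2 of day 3 the counts were 168 and 369 and without replicate 2 of day 1 196 and 439. The higher clones numbered 381 without replicate 1 of day 1 and 1058 without replicate 1 of day 3.

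Of the clones tested on both days, 92 were higher on both and 178 lower on both, where independent lists would share 15.2 and 44.5. In opposite directions 14 were higher on day 1 and lower on day 3, and 24 the reverse, where independent lists would share 34.5 and 19.6. Across clones the fitted ratios of both days correlated with r = 0.253 and a covariance of 0.046, while simulated clones with no effect, linked only by the shared dye term, gave r = 0.037 and a covariance of 0.001. The simulation drew noise independently per array, whereas deviations of arrays with the same number correlated with r = 0.046, 0.596 and 0.451. Its values for no effect may thus be too low. The shares for independent lists may be too low as well, because each clone has 1 spread for both days.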

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

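The tests of a swapped array and of different plants reported here were chosen after the result was seen, and the test of the dye bias and the regroupings of arrays were planned before it. The difference between the days, which brings these results here, was tested in one model and passed in 578 clones with the higher ratio on day 3 and 462 with the lower one. Clones are named here by the smallest p of the difference and not by its size. With the higher ratio on day 3 these were carbonic anhydrase STMCR16 (3.18), the ion channel STMIT24 (2.06), the epidermis-specific glycoprotein STMDF40 (2.25) and the unannotated clones STMDZ44 (2.47) and STMDI82 (2.16). Hypothetical tomato proteins STMGI29 (-4.68) and STMCN85 (-4.43), Ghfe1 STMCH16 (-3.87), the unannotated clone STMDH95 (-3.69) and DIMINUTO STMGG42 (-3.13) had the lower ratio on day 3. Lists whose difference passed with camera at its preset correlation had median differences of 1.40 (carbon fixation and photorespiration), 1.18 (plastid ribosomal proteins), 0.98 (chlorophyll and carotenoid synthesis), 0.68 (photosystems and light harvesting), 0.34 (nitrogen and sulfur assimilation), 0.31 (cytosolic ribosomal proteins), -0.14 (transcription factors), -0.15 (proteolysis and ubiquitin, -0.145 before rounding) and -0.42 (proteinase inhibitors). With an estimated correlation 0 of these lists passed, with adjusted p from 0.533 to 0.68, and fry for one direction called 1 list, photosystems and light harvesting (adjusted p = 0.0416).

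Replicate 1 of day 3 stood apart within its day: on it, 140 photosynthesis clones lay above replicate 3 by a median of 0.54. The median gap was 1.09 in carbon fixation and photorespiration and 0.17 in photosystems and light harvesting. A swap of salt and control on that array is argued against: of 147 clones beyond 1 on both other arrays, 98.6% kept their sign on it. A smaller dye bias on that array is argued against too. Both readings hold only if the ratios of all arrays already run one way. The day 1 dye term of the photosynthesis clones had a median of 0.046 and did not follow the gap across clones (r = -0.04). It was between 0.033 and 0.196 of the gap (95% interval from a bootstrap over clones, which carries no spread between arrays). A different response of the plants of this replicate may account for it and stays open. Of 23 lists outside photosystems and carbon fixation, 7 differed by over 0.3 between replicates 1 and 3, against 0 between replicates 2 and 3. Of these, plastid ribosomal proteins (0.871) and chlorophyll and carotenoid synthesis (0.412) are close to photosynthesis, while others, such as proteinase inhibitors (-0.365), are not. No second array of these plants was used here, so plants cannot be told from the array. That array also missed 1.12% of clones, against 14.91% and 25.07% on replicates 2 and 3.

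Other assignments of the arrays bear on chance. With salt and control exchanged on some arrays of day 1, the real assignment gave 1800 calls and the highest of the others 0, and on day 3 579 against 1. In each case 1 of 4 assignments, the real one, reached the real count, and 4 are too few for a share under 0.05. Of 10 splits of the 6 arrays into 3 and 3, 1 reached the 1040 calls of the difference between the days and the highest other gave 0, and 10 are too few as well. For the average, 1 of 30 assignments that could be fitted reached the 1611 calls. The highest other gave 1040, in the assignment that exchanges salt and control on every day 3 array, which is the comparison of the days. Chance is not excluded by these counts, because the direction taken for the arrays rested on their agreement, which itself raises the calls. This limit holds for the assignments of each day too.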

How the results depend on the processing

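Centring on the median, the authors' deposited test and the added lists were chosen after the result was seen, and the other alternatives were planned. Counts stayed within 1.5 times the reported one, with these exceptions. Without a dye term, 114 clones were higher on day 3, and 375 higher and 281 lower in the difference between the days. With arrays scaled to equal spread, 351 were higher on day 3, and with an adjusted p under 0.1, 338. The arrays of a day alone gave 470 higher clones on day 1 and, on day 3, 78 higher and 267 lower. The authors' deposited test with adjustment gave 0 higher and 0 lower clones on day 1 (2033 at an unadjusted p under 0.05, against 3027 with limma), and 1 higher and 0 lower on day 3.

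Leaving out each array in turn gave 169 to 1147 higher and 367 to 1387 lower clones on day 1, 28 to 278 and 143 to 528 on day 3, 134 to 708 and 174 to 489 for the difference, and 168 to 1058 and 369 to 1387 for the average. Fewer arrays leave fewer degrees of freedom. Both days share the spread and the dye term of a clone, so leaving out a day 3 array also alters the calls of day 1. The rise of counts without replicate 1 of day 3 was not traced further. Numbers were not taken to pair the days, since the plants differed. Deviations of same-numbered arrays correlated with r = 0.046, 0.596 and 0.451, and replicate 2 alone had salt in Cy5. Across numbers, replicates 1 and 3 gave 0.198 (replicate 1 of day 1) and 0.059 (replicate 3 of day 1), in the same dye orientation. An effect shared by arrays of the same number is thus not excluded. The p-values of the average take the arrays as independent and may be too low. A replicate block in place of the dye term gave 280 higher clones on day 3, and moved no other count by over 1.5 times.

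The 14, 5, 9 and 17 lists past the threshold on day 1, on day 3, in the difference and in the average became 0, 0, 0 and 0 with an estimated correlation. Fry for one direction gave 11 on day 1, of which 8 were among the 14 of camera. It gave 0 on day 3, 1 in the difference and 10 in the average. Fry for either direction gave 24 on day 1, 21 on day 3 and 23 in the difference. The cause was not tested. On day 3, 8 lists passed without a dye term and 5 to 10 with one array left out. The carbon fixation list, not past the threshold on day 3, was lower there by camera without replicate 1 of day 3 (adjusted p = 5.45e-05). It was higher without replicate 2 or 3 of day 3 (adjusted p = 0.000722 or 5.77e-05). Its camera adjusted p with one array left out reached 0.719, and with an estimated correlation on all arrays it was 0.981. Without the methionine matches the defence list had camera adjusted p = 0.05, upward, on day 1, where the full list had 0.653, downward. Without accidental matches the transport list had 0.0247 against 0.105, both downward. With an estimated correlation both cleaned lists had adjusted p = 0.453.

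Not run, for want of intensities here: no background correction, plain subtraction, undoing the loess, leaving out dim clones and a variance trend on signal. The series value table holds the same ratios. Among the largest rises and falls of each day and of the average, STMEK04 and STMIK39 on day 3 lost their call without replicate 2 of day 3, and the others kept theirs in every alternative that gave a value except the authors' deposited test.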

Other observations

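All tests of the sterol clones reported here were chosen after the result was seen. Among the leading day 3 falls were enzymes of sterol and steroidal glycoalkaloid synthesis, the pathway to the bitter alkaloids of potato. A list of this pathway, written after those clones were seen, had 19 of 36 clones lower on day 3 and 0 higher (23 and 0 adjusted over the list alone), with a median of -0.59. On day 1, 5 of 37 were lower and 0 higher (camera adjusted p = 0.0221, downward, and adjusted p = 0.453 with an estimated correlation). The ratio was lower on day 3 than on day 1 in 11 of 36 (camera adjusted p = 1.72e-06, and adjusted p = 0.635 with an estimated correlation). Among its members, picked after their values were seen, the glycoalkaloid rhamnosyltransferase (STMEH84) fell by 3.08 (SE 0.13), sterol desaturase (STMEA40) by 2.02 and obtusifoliol demethylase (STMEB65) by 1.91 (SE 0.12). Camera gave adjusted p = 1.51e-17 for the list, and 0.302 with an estimated correlation.

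A candidate explanation is that the pathway fell as a whole, as a hypothesis found on these data. If the ratios already run one way, a dye bias is argued against: the list's medians on the day 3 arrays lay between -0.621 and -0.518. The first of these was on the array with salt in Cy5. That direction was itself taken from agreement between opposite dye orientations, so a dye bias in unturned ratios is not excluded. A few strong clones as the whole pattern are argued against, since the 30 members outside the clones seen before the list was written had a median of -0.413 (95% bootstrap interval -0.686 to -0.286), with 13 lower and 0 higher (camera adjusted p = 2.31e-11, and adjusted p = 0.406 with an estimated correlation). A fall common to plastid and cytosolic isoprenoid synthesis stays open. The 13 clones of the plastid pathway, 2 of them lower and 0 higher on day 3, had a median of -0.256. The 95% bootstrap interval over clones, from -0.36 to -0.048, held the bound of -0.294, which was set from the sterol list's own median. Some of these clones shared an annotation, such as deoxyxylulose phosphate reductoisomerase at -0.256, -0.32, -0.412 and -0.341. The median and interval may thus count some genes repeatedly. The authors' normalization was not tested and stays open.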
